A study of Homo sapiens with 6 samples.

How the data were processed

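Messenger RNA was sequenced from 3 human lung cancer cell lines in conventional culture, with 2 libraries each: PC9, a lung adenocarcinoma line with a mutant EGFR, and its sublines PC9-BrM4 and PC9-AMG. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the TruSeq Stranded mRNA kit. The series description names a NextSeq sequencing kit. What AMG stands for is not given in the sources used here.

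The authors deposited 1 gene abundance table per library, with TPM (transcripts scaled to a fixed total), FPKM (fragments scaled by length and library size) and mean coverage per gene. Per the file headers, each gene also carries a symbol, a chromosome, a strand, a start and an end. The submitters' processing notes name bcl2fastq, HISAT2 2.1.0, StringTie 1.3.4d and the human build hg38, without saying which step each did. The annotation release and the mapping options are not given in the sources used here. A table of the whole series was not used here, because its column names do not match the labels of the PC9-AMG samples. The tables used for PC9-AMG also carry EMG in their names where the sample titles say AMG. They were assigned by the sample records, so that the values are those of PC9-AMG rests on these records. TPM fixes the total of each library, so a rise of some abundant genes lowers the values of the others, and values are relative within a library.

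Symbols on several lines of a table were summed, which left 26485 genes. The tables listed no mitochondrially encoded transcript. The ratio of the deposited coverage to the deposited FPKM gives the aligned bases behind a library, from 2.66 to 4.39 gigabases. It is the median over lines with FPKM above 0, and 60.9% to 61.2% of these lines per library lay at it, so it is an estimate. Read counts could not be recovered, because low coverage values did not step by whole reads, so no counting interval is given. Sampling noise alone would keep the median chi-square between the replicates of a line level over abundance, whatever the read length. From the lowest to the highest of 5 abundance groups of genes it rose 3.20-fold in PC9, 12.35-fold in PC9-BrM4 and 12.98-fold in PC9-AMG, so no pair was treated as a single library; this check was chosen after the data were seen.

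Values were taken to log2(TPM + 1), and a gene was tested where TPM was at least 1 in at least 2 of the 6 libraries, which kept 14195 genes. Fold changes are on that scale, which understates the change of low genes. A linear model of all 6 libraries with 1 mean per line was fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend. The model has 3 residual degrees of freedom, and the threshold was a Benjamini-Hochberg adjusted p of 0.05. The comparisons were PC9-BrM4 with PC9, PC9-AMG with PC9, and PC9-AMG with PC9-BrM4. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

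There were 26 gene lists: epithelial markers, mesenchymal markers, lung lineage, MAPK output, ERBB and other receptor kinases, interferon-stimulated genes, MHC class I presentation, NF-kB targets and cytokines, brain metastasis genes from the literature, glutamate and GABA receptors and transporters, neuronal and neuroendocrine markers, Wnt and planar polarity, proteases and inhibitors, cell adhesion, proliferation, hypoxia and glycolysis, cholesterol and fatty acid synthesis, unfolded protein and amino acid stress, YAP and TEAD targets, NRF2 targets, markers of astrocytes, of microglia and leukocytes, of oligodendrocytes and of fibroblasts and endothelium, mitochondrially encoded mRNAs, and dissociation and immediate early genes. Lists with at least 5 tested members (24 of the 26) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. With a correlation estimated by limma's camera, 0 of the 24 lists passed after adjustment in any comparison, and 1, 2 and 2 lists had an unadjusted p under 0.05 (PC9-BrM4 with PC9, PC9-AMG with PC9, PC9-AMG with PC9-BrM4). Limma's fry gave 19, 20 and 21 lists under an unadjusted p of 0.05. It asks whether the members shifted together in a direction, and not whether they changed more than other genes. The design, the lists, the gene-naming rule and the alternative settings below, apart from the last 3, were set before the data were examined.

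The genes named are, per comparison, the 6 largest rises and the 6 largest falls among called genes with a mean of at least 10 TPM in the higher group and no overlap between libraries, 2 or 3 leading members of each called list with as many that moved the other way, and fixed genes (PRICKLE1, REST, WNT5A, EGFR, MET, AXL, CDH1, VIM, NKX2-1 and L1CAM). The rule had a limit of about 30 genes per comparison, filled from the list with the smallest adjusted p. Past that limit the text adds the leading members of each remaining called list, and gives those that moved the other way mostly as counts. Some genes that the rule names are not reported here.

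The scripts were tested on simulated libraries with known changes. For a log2 change of 0.5, 68.7% (PC9-BrM4 with PC9), 70.1% (PC9-AMG with PC9) and 72.7% (PC9-AMG with PC9-BrM4) of the changed genes were recovered, among 13842, 13852 and 13840 genes. For a log2 change of 1, the shares in the same order were 100%, 96.9% and 100%, and for a log2 change of 2 they were 97.0%, 100% and 100%. Unchanged genes made up 7.94%, 6.91% and 6.35% of the calls, and 0 of 24 lists were called. Simulated genes varied independently, so the list count does not show how often lists are called falsely where genes vary together.

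The alternative settings were pseudocounts of 0.1 and 5 TPM, no filter, a mean of at least 5 TPM, median-of-ratios rescaling, quantile normalization, only the 2 groups compared, no mean-variance trend, the replicate number as a block, each library left out, a 2-fold minimum, and the estimated correlation. Added after seeing the data were 3 more: leaving out genes that overlap another on the same strand (1963 genes), subtracting the regional median within windows of 10 Mb, and subtracting each library's trend with GC content. GC content came from a reference transcript set of the same build and was matched for 13342 of the 14195 tested genes (94.0%), with a lowess span of 0.3.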

Results

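Transcript levels were compared between PC9, a human lung adenocarcinoma line with a mutant EGFR, and its sublines PC9-BrM4 and PC9-AMG, with 2 libraries per line. PC9-BrM4 is known from earlier work as a brain-metastatic derivative of PC9, which the labels do not state. The aligned sequence behind the libraries came to 3.42 and 2.66 gigabases in PC9, 3.13 and 3.84 in PC9-BrM4, and 3.93 and 4.39 in PC9-AMG. Between 13455 and 13764 genes reached 1 TPM per library. The most abundant transcript was that of the glycolytic enzyme GAPDH in each library, at 11609 to 12817 TPM, and the 10 most abundant genes took 5.03% to 5.53% of the total. Across genes, which are not independent replicates, log2 values correlated at 0.994 (PC9), 0.994 (PC9-BrM4) and 0.996 (PC9-AMG) within a line and at 0.964 to 0.974 between lines. The median absolute log2 difference between the replicates of a line was 0.0622, 0.0868 and 0.0810 in the same order. Means below carry the SD of 2 libraries (n = 2), and each gene said to have risen or fallen had libraries that did not overlap between the lines.

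The comparison of PC9-BrM4 with PC9 asks which genes distinguish the brain-metastatic subline from the parental line in culture. CEACAM6, a carcinoembryonic antigen family glycoprotein of the epithelial surface (chromosome 19, 41755520 to 41772208, hg38), fell from 596 ± 8.44 TPM in PC9 to 2.19 ± 0.0441 TPM in PC9-BrM4 (SD, n = 2). Its relative CEACAM5 stood at 15.4 ± 0.125 and 0.0213 ± 0.0301 TPM. CALML5, a calmodulin-like protein of differentiating epidermis (chromosome 10, 5498695 to 5499570), rose from 2.34 ± 0.327 to 129.6 ± 11.2 TPM. L1CAM, a neural cell adhesion molecule (chromosome X, 153861514 to 153886174), rose from 37.6 ± 0.411 to 124 ± 16.6 TPM. The log2 fold changes were -7.55 for CEACAM6, -4.0 for CEACAM5, 5.29 for CALML5 and 1.69 for L1CAM (limma adjusted p = 5.26e-09, 6.39e-07, 3.24e-07 and 9.91e-06).

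The carboxypeptidase CPVL rose from 1.58 ± 0.0389 to 63.0 ± 4.65 TPM, ANKRD35 from 1.76 ± 0.318 to 40.8 ± 2.21 TPM, and the LIM-domain protein FHL1 from 1.33 ± 0.0797 to 31.6 ± 0.434 TPM. The growth factor PTN fell from 16.9 ± 0.302 to 0.273 ± 0.0184 TPM. KYNU, which breaks down kynurenine, fell from 66.8 ± 2.96 to 5.65 ± 0.511 TPM, and the diamine oxidase AOC1 from 13.6 ± 0.495 to 0.444 ± 0.142 TPM. UGT1A8 and UGT1A10, glucuronosyltransferase models that share exons, were listed at 0 in both PC9 libraries and at 42.5 and 54.1 TPM, and 53.1 and 39.5 TPM, in the PC9-BrM4 libraries. The readthrough model ISY1-RAB43 was listed at 31.7 and 29.9 TPM in PC9 and at 0 in both PC9-BrM4 libraries. These 3 models overlap others on the same strand and are uncertain. The summed TPM over the overlapping models differed 1.10-fold for UGT1A and 1.01-fold for ISY1 and RAB43. For UGT1A this ratio alone cannot tell whether reads are shared, because UGT1A8 and UGT1A10 are small beside the sum. The sum itself did not rise with them, at 455 TPM in PC9-BrM4 against 499 TPM in PC9.

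Cholesterol and fatty acid synthesis genes were lower in PC9-BrM4. Of 33 tested members, 24 fell, 2 rose and 7 did not pass, with the same counts adjusted over the list alone (median log2 fold change -0.32). The list passed limma's camera test (adjusted p = 4.18e-06, and adjusted p = 0.711 with an estimated correlation). STARD4, a carrier of cholesterol between membranes, fell from 31.4 ± 0.579 to 9.52 ± 0.389 TPM, and HSD17B7, a sterol synthesis enzyme, from 71.05 ± 2.29 to 42.2 ± 1.23 TPM. FASN, the fatty acid synthase, rose from 295 ± 2.47 to 447 ± 70.8 TPM, and PMVK, a mevalonate pathway kinase, from 56.1 ± 2.20 to 76.2 ± 0.4 TPM. HSD17B7 has a near-identical copy, so its value is uncertain.

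Targets of NRF2, the regulator of the antioxidant response, were also lower in PC9-BrM4. Of 27 members, 17 fell, 1 rose and 9 did not pass (18 and 1 adjusted over the list alone), with a median of -0.27. Limma's camera gave an adjusted p = 3.17e-05, and an adjusted p = 0.319 with an estimated correlation. The aldo-keto reductase AKR1B10 fell from 497 ± 27.1 to 108 ± 3.24 TPM and UGDH, which makes UDP-glucuronate, from 92.0 ± 3.38 to 30.5 ± 0.676 TPM. CBR1, a carbonyl reductase, was the member that rose, from 112 ± 0.913 to 151 ± 3.48 TPM.

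MAPK output and MHC class I presentation genes were higher and proteases lower in PC9-BrM4. Of 20 MAPK output genes 11 rose and 2 fell (median 0.20), with EPHA4, an ephrin receptor, at 24.8 ± 1.57 against 8.67 ± 0.464 TPM and SPRY2, a feedback inhibitor of receptor kinases, at 41.8 ± 0.658 against 22.9 ± 0.182 TPM. DUSP6 was among the members that fell, at 12.8 ± 0.235 against 17.4 ± 0.0706 TPM (limma adjusted p = 0.0174). Its call ended without the filter (limma adjusted p = 0.0567) and with any PC9 or PC9-BrM4 library left out (log2 -0.44 to -0.40). DUSP6 lies on chromosome 12 at 80 to 90 Mb, where 93.3% of 15 tested genes were lower in PC9-BrM4 (median -0.62). With the regional median removed its log2 fold change turned to 0.16, so its fall cannot be told from that of its region. Of 17 MHC class I genes 9 rose and 2 fell (median 0.23), with HLA-B at 157 ± 0.937 against 59.2 ± 2.05 TPM and HLA-F at 14.4 ± 2.13 against 6.29 ± 0.195 TPM, both uncertain because class I genes are similar in sequence. Of 31 proteases and inhibitors 17 fell and 6 rose (median -0.22), with the metalloproteinases MMP28 at 0.25 ± 0.181 against 2.99 ± 0.608 TPM and MMP7 at 0.273 ± 0.0871 against 1.78 ± 0.659 TPM. The counts were the same adjusted over the list alone, and each of the 3 lists had an adjusted p = 0.0361 in limma's camera, or an adjusted p = 0.711, 0.509 and 0.509 with an estimated correlation. Each of these 3 calls ended in 7 of 18 other settings, with adjusted p from 0.00327 to 0.162 for MAPK output, 0.0145 to 0.162 for MHC class I and 0.0171 to 0.117 for proteases. Leaving out a library ended the MAPK call (0.0599 without PC9 replicate 1, 0.0610 without PC9-BrM4 replicate 2), the MHC class I call (0.0948 without PC9-BrM4 replicate 1) and the protease call (0.0599 and 0.117 without PC9 replicate 1 and 2, 0.0628 without PC9-BrM4 replicate 2).

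The other lists did not pass limma's camera in this comparison. Among lineage lists, 7 of 24 epithelial markers rose and 11 fell (9 and 11 adjusted over the list alone; adjusted p = 0.609), 6 of 23 mesenchymal markers rose and 11 fell (adjusted p = 0.280), and 2 of 8 lung lineage genes rose and 4 fell (3 and 4 adjusted over the list alone; adjusted p = 0.319). Of 19 brain metastasis genes from the literature 8 rose and 4 fell (10 and 5 adjusted over the list alone; adjusted p = 0.246). Part of that literature used PC9 derivatives, so this list is not independent evidence of its direction. Of 19 glutamate and GABA receptor and transporter genes 10 rose and 3 fell (10 and 4 adjusted over the list alone; adjusted p = 0.235), and of 10 neuronal and neuroendocrine markers 5 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.246). Receptor kinases split 7 up and 5 down of 19 (adjusted p = 0.637), interferon-stimulated genes 13 and 6 of 33 (14 and 7 adjusted over the list alone; adjusted p = 0.315), and NF-kB targets 8 and 4 of 19 (adjusted p = 0.319). Wnt and planar polarity genes split 11 up and 9 down of 30 (11 and 11 adjusted over the list alone; adjusted p = 0.970), cell adhesion 8 and 13 of 27 (adjusted p = 0.280), proliferation 9 and 16 of 36 (10 and 17 adjusted over the list alone; adjusted p = 0.246), and hypoxia and glycolysis 8 and 15 of 33 (10 and 15 adjusted over the list alone; adjusted p = 0.318). Stress genes of the unfolded protein response split 9 up and 7 down of 29 (adjusted p = 0.585), and YAP and TEAD targets 9 and 6 of 21 (11 and 6 adjusted over the list alone; adjusted p = 0.319). Of 21 dissociation and immediate early genes 1 rose and 7 fell (adjusted p = 0.246), a list that passed as lower with the GC trend removed (limma camera adjusted p = 0.0484, within 0.0484 to 0.330). Among markers of other cell types, 3 of 9 astrocyte genes rose and 5 fell (3 and 6 adjusted over the list alone; adjusted p = 0.318), 1 of 6 microglia and leukocyte genes rose and 2 fell (adjusted p = 0.521), and 1 of 6 fibroblast and endothelial genes rose and 4 fell (adjusted p = 0.246). Oligodendrocyte markers, with 2 of 4 higher and 0 lower, had too few members for the list test, and the mitochondrially encoded list had 0 genes in the tables. Where no second count is given, the counts adjusted over the list alone were the same. Median, mean and test differed in sign for epithelial markers (median 0.000626, mean -0.00763, test down) and Wnt genes (median -0.0808, mean 0.0862, test up).

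Among the fixed genes, EGFR, the receptor kinase mutated in this line, rose from 169 ± 12.9 to 263 ± 56.1 TPM (limma adjusted p = 0.0122). The mesenchymal filament protein VIM fell from 34.0 ± 0.0681 to 26.7 ± 0.846 TPM and the ligand WNT5A from 65.3 ± 2.64 to 45.5 ± 0.150 TPM. The receptor kinases MET and AXL fell from 202 ± 9.04 to 152 ± 9.30 TPM and from 187 ± 2.98 to 156 ± 7.0 TPM. The epithelial cadherin CDH1 rose from 79.7 ± 1.17 to 90.9 ± 5.54 TPM (limma adjusted p = 0.0285). PRICKLE1, a planar polarity protein, stood at 5.78 ± 0.256 against 7.08 ± 0.277 TPM in PC9 (limma adjusted p = 0.0612). REST, a repressor of neuronal genes, stood at 9.91 ± 0.0362 against 12.1 ± 0.646 TPM (limma adjusted p = 0.0627). Both passed in some alternative setting, with log2 fold changes from -0.29 to 0.16 for PRICKLE1 and -0.31 to -0.20 for REST over the alternatives. NKX2-1, the lung lineage factor, was listed at 0 in all 4 libraries. The EGFR call ended without PC9 replicate 2 (adjusted p = 0.0513), without PC9-BrM4 replicate 2 (0.0580) and without the filter (0.0589), within 0.00243 to 0.0589 over its alternatives in limma. The CDH1 call ended in 7 settings (limma adjusted p from 0.00805 to 0.196 over the alternatives), among them those without PC9 replicate 1 (0.0872), PC9 replicate 2 (0.133) and PC9-BrM4 replicate 2 (0.127), and MET changed sign to 0.0510 with the regional median removed.

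In all, 6608 of 14195 tested genes (46.6%) passed in limma, 3322 higher and 3286 lower in PC9-BrM4. Of these, 255 were at least 2-fold higher and 286 at least 2-fold lower. The libraries of the 2 lines did not overlap for 75.2% of the tested genes, where chance gives 33.3%.

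The comparison of PC9-AMG with PC9 asks the same of the second subline. OLR1, a scavenger receptor for oxidized lipoproteins (chromosome 12, 10158300 to 10172191), rose from 4.88 ± 0.0808 TPM in PC9 to 157 ± 0.281 TPM in PC9-AMG (SD, n = 2). MAGEA4, a cancer-testis antigen (chromosome X, 151912889 to 151925170), rose from 0.357 ± 0.271 to 20.1 ± 0.434 TPM. EDIL3, an extracellular matrix protein that binds integrins, fell from 17.6 ± 1.53 to 1.97 ± 0.0886 TPM. OXCT1, the enzyme that opens ketone body breakdown, fell from 49.0 ± 0.852 to 13.1 ± 0.174 TPM. The log2 fold changes were 4.75 for OLR1, 3.97 for MAGEA4, -2.64 for EDIL3 and -1.83 for OXCT1 (limma adjusted p = 1.95e-07, 3.44e-06, 2.51e-06 and 2.22e-06).

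XAGE2, another cancer-testis gene, rose from 0.383 ± 0.542 to 29.7 ± 1.60 TPM and the natriuretic peptide gene NPPB from 0.0501 ± 0.0708 to 14.5 ± 2.33 TPM. XAGE2 and MAGEA4 belong to families of similar copies, so their values are uncertain. CEACAM5 fell from 15.4 ± 0.125 to 3.50 ± 0.369 TPM, and the complement component C3 from 32.5 ± 0.000386 to 8.44 ± 0.0986 TPM. TNFAIP2, a target of tumor necrosis factor, fell from 154 ± 6.05 to 42.0 ± 0.229 TPM, and IFT43, an intraflagellar transport protein, from 133 ± 0.555 to 37.0 ± 0.466 TPM. TNFAIP2 and IFT43 lie on chromosome 14 within stretches whose 14 and 21 tested genes were all lower in PC9-AMG, with median log2 fold changes of -1.21 and -1.22. The readthrough models MINOS1-NBL1 and BCL2L2-PABPN1 were listed at 0 in both PC9 libraries and at 17.6 and 18.1 TPM, and 16.0 and 7.83 TPM, in the PC9-AMG libraries. Both are uncertain, since they overlap other models on the same strand. The summed TPM over their overlapping models differed 1.02-fold and 1.13-fold. Both models are small beside these sums, so the ratios alone cannot tell whether reads are shared. The sums themselves did not rise, at 90.9 against 92.6 TPM and 108 against 122 TPM in PC9.

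Genes of the unfolded protein response and amino acid stress rose together in PC9-AMG. Of 29 tested members, 23 rose, 1 fell and 5 did not pass, with a median log2 fold change of 0.54. Limma's camera gave an adjusted p = 1.77e-06, and an adjusted p = 0.523 with an estimated correlation. The stress transcription factor ATF3 rose from 6.92 ± 0.0315 to 34.7 ± 4.58 TPM and CHAC1, which degrades glutathione, from 11.2 ± 0.258 to 32.6 ± 6.19 TPM. PSPH, the last enzyme of serine synthesis, fell from 112 ± 0.370 to 88.2 ± 4.69 TPM. Dissociation and immediate early genes, which respond within minutes to handling and to growth factors, moved in the same direction, with 14 of 21 higher and 1 lower (median 0.64, limma camera adjusted p = 0.000252, and adjusted p = 0.399 with an estimated correlation). Among them the phosphatase DUSP1 rose from 9.10 ± 0.336 to 53.1 ± 9.62 TPM.

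Cholesterol and fatty acid synthesis genes were higher in PC9-AMG. Of 33 members 22 rose, 3 fell and 8 did not pass, with a median of 0.35 (limma camera adjusted p = 0.000148, and adjusted p = 0.523 with an estimated correlation). FASN rose from 295 ± 2.47 to 547 ± 25.1 TPM and DHCR7, the last enzyme of cholesterol synthesis, from 373 ± 12.1 to 646 ± 23.9 TPM. PMVK fell from 56.1 ± 2.20 to 43.8 ± 0.563 TPM and the isomerase IDI1 from 314 ± 4.07 to 265 ± 24.0 TPM. The IDI1 call ended without PC9 replicate 2 (limma adjusted p = 0.0522) and with the GC trend removed (0.0610), and its sign turned with the regional median removed (log2 0.13), within limma adjusted p of 0.00259 to 0.169.

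NF-kB targets and cytokines, and YAP and TEAD targets, rose as well. Of 19 NF-kB targets 14 rose and 2 fell (15 and 2 adjusted over the list alone), with a median of 0.90, a limma camera adjusted p = 0.000252 and an adjusted p = 0.4 with an estimated correlation. RELB, an NF-kB subunit, rose from 3.30 ± 0.757 to 24.4 ± 1.10 TPM and the adhesion molecule ICAM1 from 15.6 ± 0.508 to 73.0 ± 2.91 TPM, while TNFAIP2 is 1 of the 2 that fell. Of 21 YAP and TEAD targets 13 rose and 2 fell, with a median of 0.45, a limma camera adjusted p = 0.000252 and an adjusted p = 0.523 with an estimated correlation. CTGF, a matricellular protein, rose from 14.4 ± 0.435 to 94.4 ± 2.99 TPM and the kinase NUAK2 from 2.79 ± 0.214 to 19.2 ± 0.590 TPM. The immediate early list, with its median of 0.64, moved in the direction of both groups.

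Epithelial markers, interferon-stimulated genes and MHC class I genes were higher and proliferation genes lower in PC9-AMG. Of 24 epithelial markers 16 rose and 4 fell (median 0.21), among them the tight junction proteins CLDN3, from 8.60 ± 0.878 to 32.7 ± 0.229 TPM, and OCLN, from 12.3 ± 0.354 to 29.7 ± 3.51 TPM. Of 33 interferon-stimulated genes 17 rose and 1 fell (median 0.28), with IFI6 at 15.4 ± 0.2 against 5.46 ± 1.20 TPM and the exonuclease ISG20 at 4.13 ± 0.546 against 1.05 ± 0.284 TPM. Of 17 MHC class I genes 11 rose and 2 fell (median 0.24), with the peptide transporter TAP1 at 29.9 ± 1.17 against 14.1 ± 0.204 TPM and HLA-B at 121 ± 0.712 against 59.2 ± 2.05 TPM. Of 36 proliferation genes 18 fell and 5 rose (median -0.16). The replication clamp PCNA fell from 716 ± 19.3 to 352 ± 14 TPM and the topoisomerase TOP2A from 214 ± 0.122 to 143 ± 7.79 TPM. Limma's camera gave adjusted p = 0.00477, 0.00600, 0.00719 and 0.00758 for the epithelial, interferon, MHC class I and proliferation lists, and adjusted p = 0.399, 0.399, 0.399 and 0.454 with an estimated correlation. With the GC trend removed, the epithelial (0.0556), MHC class I (0.0535) and proliferation (0.0535) calls ended, within ranges of 0.000488 to 0.0556, 0.00162 to 0.0535 and 0.00220 to 0.0535 over the alternatives.

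The other lists did not pass limma's camera against PC9. MAPK output split 11 up and 4 down of 20 (12 and 4 adjusted over the list alone; adjusted p = 0.0507), receptor kinases 11 and 5 of 19 (adjusted p = 0.0984), and NRF2 targets 7 and 13 of 27 (7 and 15 adjusted over the list alone; adjusted p = 0.0507). NRF2 targets passed as lower in 10 of 18 other settings (limma camera adjusted p from 0.0152 to 0.0822), MAPK output as higher in 4 (0.0118 to 0.154), receptor kinases as higher in 3 (0.0135 to 0.220) and astrocyte markers as higher in 1, without PC9-AMG replicate 1 (0.0398 to 0.173). Mesenchymal markers split 9 up and 4 down of 23 (adjusted p = 0.529), lung lineage genes 3 and 3 of 8 (adjusted p = 0.818), and brain metastasis genes from the literature 9 and 5 of 19 (adjusted p = 0.595). Glutamate and GABA genes split 7 up and 7 down of 19 (9 and 8 adjusted over the list alone; adjusted p = 0.914), neuronal and neuroendocrine markers 3 and 1 of 10, Wnt and planar polarity genes 9 and 10 of 30, and proteases 14 and 12 of 31 (each adjusted p = 0.595). Cell adhesion split 7 up and 14 down of 27 (adjusted p = 0.281) and hypoxia and glycolysis 13 and 7 of 33 (adjusted p = 0.490). Markers of other cell types split 6 up and 2 down of 9 for astrocytes (adjusted p = 0.0753), 3 and 2 of 6 for microglia and leukocytes (adjusted p = 0.465), 3 and 0 of 6 for fibroblasts and endothelium (adjusted p = 0.351), and 2 and 0 of 4 for oligodendrocytes, which were too few to test as a list. Of the 19 astrocyte markers 9 also stand in another list. Where no second count is given, the counts adjusted over the list alone were the same for the lists of this comparison. Median, mean and test differed in sign for lung lineage genes (median -0.0917, mean 0.000435, test down) and proteases (median -0.00345, mean 0.0786, test up).

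Of the fixed genes, VIM fell from 34.0 ± 0.0681 to 12.5 ± 1.26 TPM, WNT5A from 65.3 ± 2.64 to 36.3 ± 0.793 TPM and PRICKLE1 from 7.08 ± 0.277 to 4.84 ± 0.450 TPM. L1CAM rose from 37.6 ± 0.411 to 110 ± 2.31 TPM, AXL from 187 ± 2.98 to 257 ± 4.01 TPM, CDH1 from 79.7 ± 1.17 to 96.3 ± 3.57 TPM and MET from 202 ± 9.04 to 230.0 ± 12.9 TPM. EGFR stood at 210 ± 34.3 against 169 ± 12.9 TPM (limma adjusted p = 0.125) and REST at 10.7 ± 1.43 against 12.1 ± 0.646 TPM (limma adjusted p = 0.176). REST passed as lower in some alternative setting (log2 -0.30 to -0.046 over the alternatives). NKX2-1 was listed at 0 in both PC9 libraries and at 0.0409 and 0 TPM in the PC9-AMG libraries. The AXL call (limma adjusted p = 0.000161) ended with the regional median removed (0.405, the highest of its alternatives, which start at 1.65e-05). The MET call (limma adjusted p = 0.0348) ended without PC9 replicate 2 (0.183), without PC9-AMG replicate 1 (0.181), without the filter, without the trend and in the replicate block (0.0548), within 0.00216 to 0.183.

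In all, 7882 of 14195 genes (55.5%) passed in limma, 3945 higher and 3937 lower in PC9-AMG. Of these, 397 were at least 2-fold higher and 236 at least 2-fold lower. Libraries did not overlap for 79.8% of the tested genes, where chance gives 33.3%. On chromosome 14 between 70 and 80 Mb, 85.9% of 71 tested genes were lower in PC9-AMG, with a median log2 fold change of -0.89.

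**Figure D1:**
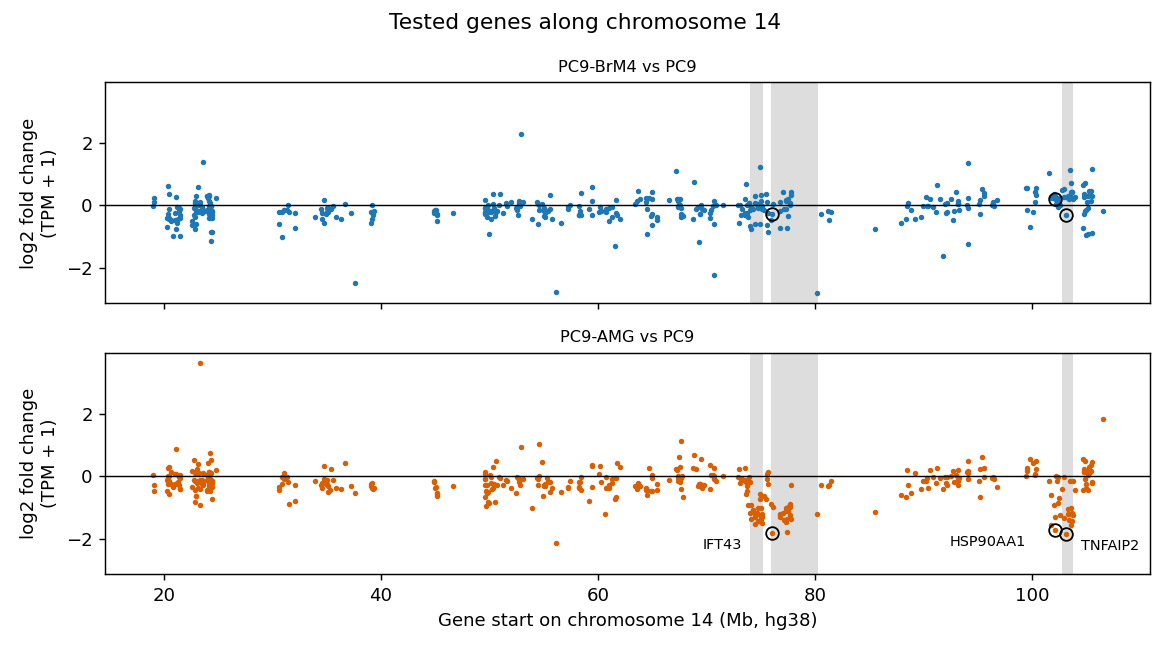
Log2 fold change (TPM + 1) of each tested gene against its start on chromosome 14 (Mb, hg38) in PC9-BrM4 and in PC9-AMG, each against PC9; points are genes and grey bands are the 3 stretches lower in PC9-AMG. In those bands the PC9-AMG medians are -1.21, -1.22 and -1.21. Circles mark IFT43 and TNFAIP2, which lie in them, and HSP90AA1, which lies outside them but within a stretch lower in PC9-AMG than in PC9-BrM4.

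The direct comparison of PC9-AMG with PC9-BrM4 asks where the sublines differ from each other. CEACAM6 was at 330 ± 36.5 TPM in PC9-AMG and 2.19 ± 0.0441 TPM in PC9-BrM4, and the membrane mucin MUC4 (chromosome 3, 195746766 to 195811973) at 61.2 ± 0.990 and 1.29 ± 0.311 TPM. C4BPB, a regulator of complement, was at 29.8 ± 4.56 and 0.352 ± 0.498 TPM. CALML5 was lower in PC9-AMG, at 3.46 ± 0.465 against 129.6 ± 11.2 TPM, as were the endotoxin receptor TLR4, at 0.213 ± 0.0333 against 12.9 ± 0.717 TPM, and the Wnt antagonist SFRP1, at 8.43 ± 1.27 against 93.0 ± 5.85 TPM. The log2 fold changes were 6.69 for CEACAM6, 4.77 for MUC4, 4.55 for C4BPB, -4.87 for CALML5, -3.52 for TLR4 and -3.32 for SFRP1 (limma adjusted p = 1.30e-08, 2.41e-07, 8.09e-06, 2.67e-07, 5.24e-07 and 6.98e-07).

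OLR1 (157 ± 0.281 against 7.42 ± 0.676 TPM) and MAGEA4 (20.1 ± 0.434 against 0.151 ± 0.0228 TPM) were higher in PC9-AMG, and ANKRD35 (1.3 ± 0.0867 against 40.8 ± 2.21 TPM) was lower. The uncertain model ISY1-RAB43 was listed at 33.9 and 41.7 TPM in PC9-AMG and at 0 in both PC9-BrM4 libraries, and UGT1A8 and UGT1A10 were listed at 0 in both PC9-AMG libraries.

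Cholesterol and fatty acid synthesis genes separated the sublines. Of 33 members 30 were higher in PC9-AMG, 1 was lower and 2 did not pass, with a median of 0.66 (limma camera adjusted p = 9.08e-11, and adjusted p = 0.511 with an estimated correlation). STARD4 was at 44.0 ± 7.35 against 9.52 ± 0.389 TPM and the sterol desaturase SC5D at 38.9 ± 4.50 against 16.1 ± 0.0881 TPM, while PMVK, the exception, was at 43.8 ± 0.563 against 76.2 ± 0.4 TPM. Dissociation and immediate early genes were higher for 17 of 21 and lower for 1, with a median of 0.57 (limma camera adjusted p = 2.73e-05, and adjusted p = 0.511 with an estimated correlation). DUSP1 was at 53.1 ± 9.62 against 6.14 ± 0.0319 TPM and ATF3 at 34.7 ± 4.58 against 4.98 ± 0.283 TPM. The transcription factor FOS was the member that was lower, at 4.53 ± 0.189 against 6.75 ± 0.195 TPM, and its log2 value turned from -0.49 to 0.20 with the regional median of chromosome 14 removed.

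Stress, epithelial, YAP and NF-kB lists were also higher in PC9-AMG than in PC9-BrM4, as was the immediate early list. Of 29 stress genes 22 were higher and 3 lower (median 0.40), with CHAC1 at 32.6 ± 6.19 against 8.54 ± 0.641 TPM and the transcription factor DDIT3 at 87.1 ± 13.9 against 34.9 ± 3.32 TPM. Of 24 epithelial markers 14 were higher and 4 lower (15 and 4 adjusted over the list alone; median 0.37), with the claudin CLDN4 at 630.3 ± 22.7 against 323 ± 0.681 TPM. Of 21 YAP and TEAD targets 14 were higher and 4 lower (14 and 5 adjusted over the list alone; median 0.34), with the growth arrest gene GADD45A at 216 ± 12.4 against 44.4 ± 1.57 TPM and CTGF at 94.4 ± 2.99 against 22 ± 0.0884 TPM. Of 19 NF-kB targets 14 were higher and 3 lower (14 and 4 adjusted over the list alone; median 0.66), with the cytokine IL11 at 47.6 ± 13.6 against 4.36 ± 0.450 TPM and RELB at 24.4 ± 1.10 against 5.27 ± 0.208 TPM. Limma's camera gave adjusted p = 0.000118, 0.00243, 0.00513 and 0.00622 for these lists in order, and adjusted p = 0.519, 0.511, 0.519 and 0.519 with an estimated correlation. The NF-kB call ended at a mean of at least 5 TPM (0.0843, within 0.00180 to 0.0843 over the alternatives).

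The other lists did not pass limma's camera between the sublines. Proteases split 16 up and 8 down of 31 and fibroblast and endothelial markers 4 and 0 of 6 (5 and 0 adjusted over the list alone; each adjusted p = 0.0857), hypoxia and glycolysis 17 and 9 of 33 (18 and 9 adjusted over the list alone) and microglia and leukocyte markers 4 and 0 of 6 (each adjusted p = 0.0911), and interferon-stimulated genes 15 and 5 of 33 (adjusted p = 0.0916). Proteases passed as higher without PC9-AMG replicate 1 (limma camera adjusted p = 0.0354, within 0.0354 to 0.189), and fibroblast and endothelial markers in 2 settings, without the filter and without the trend (0.0408 to 0.142 over the alternatives). Lung lineage genes split 5 up and 2 down of 8 (adjusted p = 0.107), astrocyte markers 6 and 3 of 9 (adjusted p = 0.224), mesenchymal markers 10 and 7 of 23 (11 and 7 adjusted over the list alone; adjusted p = 0.281), and neuronal and neuroendocrine markers 2 and 4 of 10 (2 and 5 adjusted over the list alone; adjusted p = 0.281). NRF2 targets split 12 up and 8 down of 27 (adjusted p = 0.332), brain metastasis genes 6 and 9 of 19 (6 and 10 adjusted over the list alone) and Wnt and planar polarity genes 7 and 11 of 30 (each adjusted p = 0.346), and receptor kinases 8 and 4 of 19 (adjusted p = 0.372). Glutamate and GABA genes split 4 up and 8 down of 19 (adjusted p = 0.414), cell adhesion 11 and 10 of 27 (adjusted p = 0.553), proliferation 12 and 12 of 36 (adjusted p = 0.584), MAPK output 10 and 6 of 20 (adjusted p = 0.596), MHC class I genes 7 and 3 of 17 (adjusted p = 0.645), and oligodendrocyte markers 1 and 1 of 4, untested as a list. Where no second count is given, the counts adjusted over the list alone were the same between the sublines.

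Of the fixed genes, MET (230.0 ± 12.9 against 152 ± 9.30 TPM) and AXL (257 ± 4.01 against 156 ± 7.0 TPM) were higher in PC9-AMG, and VIM (12.5 ± 1.26 against 26.7 ± 0.846 TPM) and WNT5A (36.3 ± 0.793 against 45.5 ± 0.150 TPM) were lower, with limma adjusted p = 0.000165, 1.54e-05, 3.11e-05 and 0.00156. EGFR, CDH1, PRICKLE1, REST and L1CAM did not pass in the main setting (limma adjusted p = 0.109, 0.244, 0.0868, 0.465 and 0.125). Apart from REST, each of them passed in some alternative setting. Their log2 fold changes over the alternatives ran from -0.54 to -0.10 (EGFR), 0.021 to 0.51 (CDH1), -0.56 to -0.13 (PRICKLE1) and -0.30 to -0.030 (L1CAM). In all, 7962 of 14195 genes (56.1%) passed in limma, 3984 higher and 3978 lower in PC9-AMG. Of these, 545 were at least 2-fold higher and 313 at least 2-fold lower, and libraries did not overlap for 77.5% of the genes, where chance gives 33.3%.

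**Figure D2:**
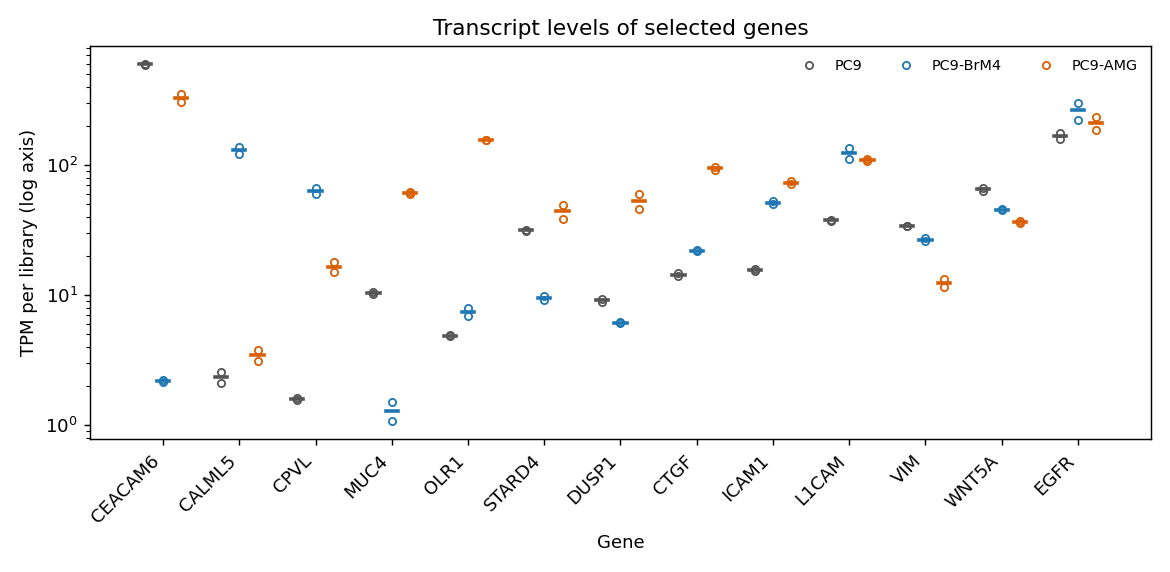
TPM per library on a log axis for 13 named genes in PC9, PC9-BrM4 and PC9-AMG; circles are libraries and bars are group means of 2 libraries. CEACAM6 lies at 2.19 TPM in PC9-BrM4 against 596 in PC9 and 330 in PC9-AMG, and OLR1 at 157 TPM in PC9-AMG.

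**Figure D3:**
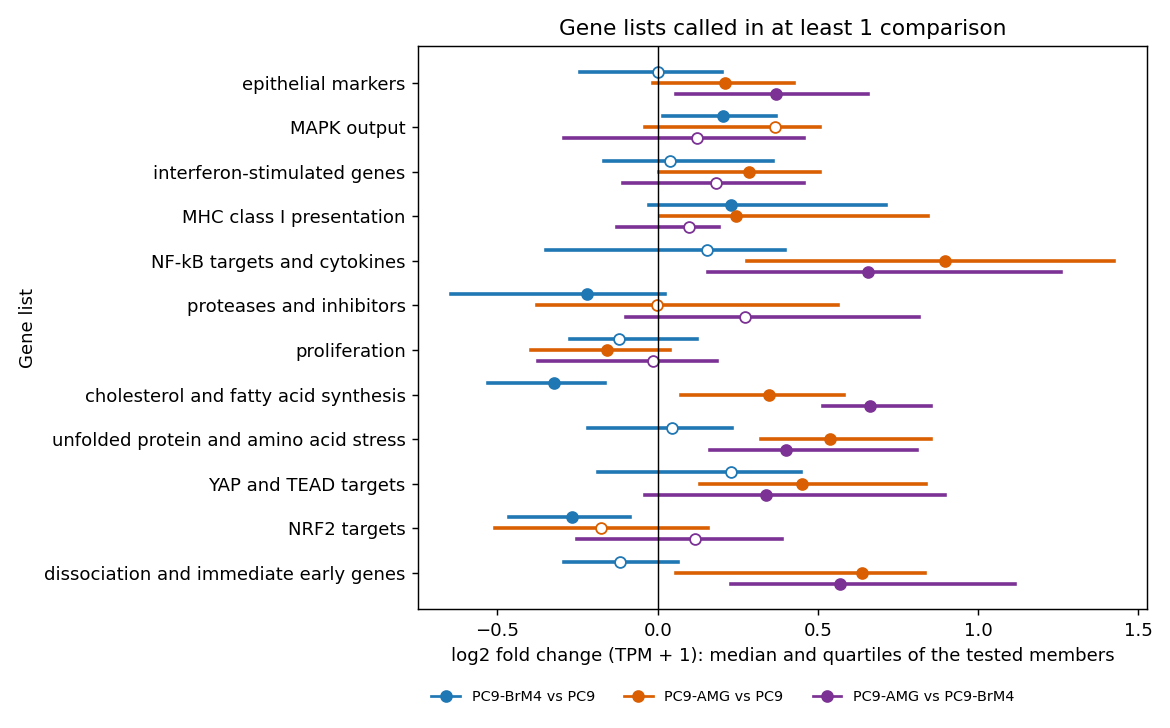
Log2 fold change (TPM + 1) of the tested members of each gene list that passed limma's camera in at least 1 comparison; points are list medians (filled where the list passed), bars run from the lower to the upper quartile, and colours are the comparisons. Cholesterol and fatty acid synthesis lies at -0.32 in PC9-BrM4 against PC9, 0.35 in PC9-AMG against PC9 and 0.66 between the sublines.

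The changes of both sublines against PC9 were then set side by side. Across 14195 genes, which are not independent replicates, the log2 fold changes correlated at 0.341. Since both comparisons use the same PC9 libraries, 100 simulations of unchanged groups gave 0.502 (SD 0.0381). The covariance was 0.0774 against 0.00731 in the simulations, a difference of 0.0701. The same sign was seen for 62.4% of genes against 66.7% simulated. The simulations hold noise alone, so the shared control sets the simulated correlation and sign share whatever the data. With 46.6% and 55.5% of genes called against PC9, the observed correlation and sign share cannot be read against them. Of the called genes, 1636 were higher in both sublines, 1552 lower in both, 515 higher in PC9-BrM4 and lower in PC9-AMG, and 574 the reverse, where independent calls would give 923, 911, 921 and 913. Part of the excess may come from the shared controls, which were not split, since a split would leave 1 PC9 library per comparison. L1CAM is among the genes higher in both, and VIM and WNT5A are among those lower in both.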

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

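The tests of GC content, of regional change and of library scaling in this part were chosen only after the result was seen. Each result here moved in opposite directions in the sublines against PC9, passed in both comparisons, and also passed in the direct comparison of PC9-AMG with PC9-BrM4. For a gene, the direct log2 fold change is the difference between its changes against PC9. With opposite signs it is larger in size than either, so for genes the direct pass was close to given and adds no support. Log2 fold changes are given for PC9-BrM4 against PC9, PC9-AMG against PC9, and PC9-AMG against PC9-BrM4, in that order. In the direct comparison, the libraries of the sublines did not overlap for any of these genes. That follows from their lying on opposite sides of the PC9 libraries.

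Most of these genes, which were drawn from the named genes, were lower in PC9-BrM4 and higher in PC9-AMG. Over all genes called in opposite directions against PC9, 574 went this way and 515 the other. The mucin MUC4 stood at -2.32, 2.45 and 4.77, the complement regulator C4BPB at -1.06, 3.50 and 4.55, and the cytokine IL11 at -1.17, 1.98 and 3.15. Stress and early response genes were DUSP1 (-0.50, 2.41, 2.91), ATF3 (-0.41, 2.17, 2.57), GADD45A (-0.39, 1.87, 2.26), the chaperone HSPB1 (-0.29, 1.64, 1.93), CHAC1 (-0.36, 1.45, 1.81) and DDIT3 (-0.32, 0.97, 1.29). The YAP target ANKRD1 stood at -0.19, 1.71 and 1.89, and the sterol genes STARD4, SC5D and CYP51A1 at -1.62, 0.46 and 2.09, at -0.47, 0.75 and 1.22, and at -0.61, 0.53 and 1.13. The epithelial gene CLDN4 (-0.12, 0.85, 0.96) and the receptor kinases AXL (-0.26, 0.46, 0.72) and MET (-0.41, 0.19, 0.59) followed. The AXL call in PC9-AMG against PC9 ended with the regional median removed (limma adjusted p = 0.405, within 1.65e-05 to 0.405). The MET call there ended in 5 settings, among them those without PC9 replicate 2 (0.183) and without PC9-AMG replicate 1 (0.181), within 0.00216 to 0.183, and in PC9-BrM4 against PC9 its sign turned with the regional median removed (0.599, within 0.000226 to 0.599).

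The others were higher in PC9-BrM4 and lower in PC9-AMG. They were TLR4 (1.51, -2.01, -3.52), SFRP1 (2.11, -1.21, -3.32), OXCT1 (0.66, -1.83, -2.49), the replication helicase subunit MCM6 (0.36, -0.50, -0.86), PMVK (0.44, -0.35, -0.79), the cadherin CDH3 (0.34, -0.21, -0.54) and the immunoproteasome subunit PSMB10 (0.23, -0.24, -0.47). Of these, the CDH3 call in PC9-AMG against PC9 ended without PC9 replicate 1 (limma adjusted p = 0.0662), PC9 replicate 2 (0.0778) or PC9-AMG replicate 1 (0.0678) and its sign turned with the regional median removed (0.157), within 0.00325 to 0.157. Its direct call ended with the regional median removed (0.114, within 1.52e-05 to 0.114). The PSMB10 call in PC9-AMG against PC9 ended without PC9 replicate 1 (0.0663) or PC9-AMG replicate 1 (0.0511) and its sign turned with the regional median removed (0.371), within 0.000979 to 0.371. Its PC9-BrM4 call ended without PC9 replicate 1 (0.0578), PC9 replicate 2 (0.0937) or PC9-BrM4 replicate 1 (0.0620), with the regional median removed (0.149) and with the GC trend removed (0.217), within 0.00973 to 0.217, and its direct call ended with the regional median removed (0.506, within 6.77e-05 to 0.506).

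Several of the calls in PC9-BrM4 against PC9 were close to the threshold in limma, so for these genes the call of opposite directions depends on the setting. CHAC1 (adjusted p = 0.0444) lost its call in 9 of 18 settings (0.0134 to 0.178), CLDN4 (0.0442) in 8 of 18 (0.0160 to 0.833) and DDIT3 (0.0452) in 8 of 17 (0.0163 to 0.275). In 1 further setting for each, with the regional median removed, the log2 fold changes of CLDN4 (0.014) and DDIT3 (0.16) reversed and did not pass (limma adjusted p = 0.833 and 0.275). Left-out libraries ended the calls of CHAC1 (PC9 replicate 1, 0.102; PC9 replicate 2, 0.137; PC9-BrM4 replicate 1, 0.0652; PC9-BrM4 replicate 2, 0.178), of CLDN4 (0.141, 0.198, 0.105 and 0.1003 in the same order) and of DDIT3 (PC9 replicate 1, 0.0835; PC9 replicate 2, 0.153; PC9-BrM4 replicate 2, 0.213). ANKRD1 (0.0250) lost its call without each of these 4 libraries (0.119, 0.114, 0.0589 and 0.0551) and with the GC trend removed (0.09996), within 0.0208 to 0.119. ATF3 lost its call without PC9 replicate 1 (0.0532) or PC9-BrM4 replicate 2 (0.0597, within 0.00534 to 0.0597), C4BPB without the filter (0.0513, within 0.00208 to 0.0513) and HSPB1 with the regional median removed (0.149, within 0.00121 to 0.149). Apart from these and from AXL, MET, CDH3 and PSMB10, the genes of this part kept their calls and directions in each comparison under the settings run. These settings leave out the 2-fold minimum, which was applied to gene counts only. Several of the changes were under 2-fold, such as those of GADD45A (-0.39) and PMVK (0.44) in PC9-BrM4 against PC9.

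The cholesterol and fatty acid synthesis list was lower in PC9-BrM4 and higher in PC9-AMG, and differed between the sublines with a median log2 fold change of 0.66 (limma camera adjusted p = 9.08e-11, and adjusted p = 0.511 with an estimated correlation). The median was 0.65 with the GC trend removed, 0.68 with the regional median removed and 0.67 after quantile normalization, which argues against GC content, a regional change and library scaling as the whole source. No biological explanation was tested. A difference in sterol synthesis between the lines stays open, as do culture density and medium at harvest, which the labels do not give.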

How the results depend on the processing

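The tests without overlapping genes, with the regional median removed and with the GC trend removed were chosen only after the results were seen. The 2-fold minimum was applied to gene counts only. Over the other settings, results for genes in the comparisons that named them kept their side of the threshold, and the direction of any call, in 2780 cases. A sign change counted as a reversal only where the result passed in the main or the other setting. Results that passed in neither may have changed sign uncounted, as PRICKLE1 did in PC9-BrM4 against PC9 (log2 -0.29 to 0.16). They lost a call in 62, gained one in 17 and reversed in 9. For list tests the counts were 1289, 45, 22 and 0.

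Asking for at least a 2-fold change left 541 genes for PC9-BrM4 against PC9, 633 for PC9-AMG against PC9 and 858 for PC9-AMG against PC9-BrM4, because the rule itself removes smaller changes. The lists called for PC9-BrM4 against PC9 went from 5 to 2 at a mean of at least 5 TPM, to 3 after quantile normalization, to 2 without the mean-variance trend, to 2 without genes that overlap on the same strand and to 3 with the regional median removed, and lay between 3 and 5 with a library left out. The cause was not tested. With an estimated correlation 0 lists were called by limma's camera in each of the comparisons. With a library left out, PC9-AMG gave 10 to 12 lists against PC9 and 6 to 7 against PC9-BrM4, where the lone library of a line is assumed to vary like the other lines.

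The correlation of the fold changes of the sublines, 0.341, was 0.357 with a pseudocount of 0.1 TPM, 0.325 at a mean of at least 5 TPM, 0.354 with the regional median removed, 0.3001 with the GC trend removed, and 0.332 to 0.361 with a library left out. The cause was not tested.

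With the regional median removed, the log2 fold changes of some called genes reversed. They were DUSP6 (0.16) and MET (0.051) in PC9-BrM4 against PC9, and FOS (0.20) in PC9-AMG against PC9-BrM4. In PC9-AMG against PC9 they were IDI1 (0.13), FOS (0.21), CDH3 (0.11), PSMB10 (0.073), BIRC5 (-0.12) and TK1 (-0.13). CLDN4 (0.014) and DDIT3 (0.16) reversed as well in PC9-BrM4 against PC9. CLDN4 and DDIT3 are not in the total of 9 above, because the naming rule did not name them in that comparison. By construction this setting subtracts the change of a gene's neighbours.

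Treating the replicate number as a block gave 6126, 7457 and 7599 genes and 5, 9 and 6 lists in the order above. The replicate differences of the lines correlated at -0.0691, -0.0277 and -0.0627, so the numbers do not pair the libraries. In the block, MET in PC9-AMG against PC9 (limma adjusted p = 0.0548) and TNFAIP3 in PC9-AMG against PC9-BrM4 (0.0544) lost their calls. So did CLDN4 in PC9-BrM4 against PC9 (limma adjusted p = 0.0699).

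With a library left out, limma called 4563 to 6352 genes for PC9-BrM4 against PC9, 5981 to 8124 for PC9-AMG against PC9 and 6373 to 7554 for PC9-AMG against PC9-BrM4. Aligned sequence of 2.66 to 4.39 gigabases limits genes near 1 TPM, where the pseudocount shrinks the fold change.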

Other observations

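All tests of regions, gene families and overlapping models in this part were chosen only after the values were seen. The 5 tested CEACAM genes all fell in PC9-BrM4 against PC9 (median log2 fold change -2.64), and all 5 were higher in PC9-AMG than in PC9-BrM4 (median 2.12), while in PC9-AMG against PC9 3 fell and 1 rose (median -0.52), with the same counts after quantile normalization and median-of-ratios rescaling. CEACAM1 stood at 2.11 ± 0.383 TPM in PC9, 0.322 ± 0.0487 in PC9-BrM4 and 2.26 ± 0.054 in PC9-AMG, and CEACAM3 at 5.30 ± 0.431, 0.0119 ± 0.0168 and 3.41 ± 0.223 TPM (n = 2). These genes belong to a family of similar copies, and CEACAM3 was lowest in PC9-BrM4, as the far more abundant CEACAM6 was. Their values are therefore uncertain, and the 5 changes may not be independent. Of 32 tested cancer-testis genes, whose copies are similar, 15 rose and 3 fell in PC9-AMG against PC9 (16 and 3 with either rescaling), and 9 rose and 8 fell in PC9-BrM4 (10 and 6 after quantile normalization). MAGEA3 stood at 278 ± 3.39, 381 ± 4.48 and 330 ± 12 TPM.

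Of 14 tested HOX genes, 9 fell and 1 rose in PC9-BrM4 against PC9 (7 and 1 after quantile normalization). The 9 that fell were the 5 tested HOXC and the 4 tested HOXB genes (4 and 3 after quantile normalization), whose windows, chromosome 12 at 50 to 60 Mb and chromosome 17 at 40 to 50 Mb, had medians of -0.50 and -0.21. In PC9-AMG 6 fell and 1 rose (6 and 0 after quantile normalization). Between the sublines the median was 0.10, and it changed sign after quantile normalization (-0.00154). HOXC6 stood at 4.62 ± 0.187 TPM in PC9, 0.963 ± 0.465 in PC9-BrM4 and 2.26 ± 0.0953 in PC9-AMG, and HOXB7 at 45.2 ± 1.63, 30.9 ± 1.26 and 22.1 ± 0.107 TPM.

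Neighbouring genes changed together in places. In PC9-AMG against PC9, 3 stretches of chromosome 14 were lower: 73966478 to 75176646 (20 genes), 75958097 to 80231054 (21 genes) and 102777479 to 103733668 (14 genes), with medians of -1.21, -1.22 and -1.21, where the same genes had medians of -0.05, 0.04 and 0.36 in PC9-BrM4. On chromosome 1, 36155965 to 36385927 (5 genes) and 40861056 to 41484683 (6 genes) were higher in PC9-AMG, with medians of 1.23 and 1.32 (0.52 and 0.42 in PC9-BrM4). In PC9-BrM4, 11 genes of chromosome 12 from 53711118 to 54351851, the HOXC genes among them, had a median of -0.82. The longest stretches spanned 11, 21 and 26 genes in the comparisons, against 0, 4 and 4 in 100 permuted gene orders. Windows of 10 Mb with at least 10 tested genes were also tested. The median of each was set against 10000 random draws of as many genes, with a Benjamini-Hochberg adjusted p under 0.05. Genes are the unit of this test, so the spread between libraries plays no part in it. Of 289 windows, 58 passed in PC9-BrM4 against PC9 (24 higher, 34 lower), 59 in PC9-AMG against PC9 (26 and 33) and 58 between the sublines (31 and 27). With the GC trend removed, 45, 54 and 58 of 284 windows passed, and 39, 40 and 52 passed both ways in the same direction. Among the calls that ended were chromosome 19 at 0 to 10 Mb in PC9-BrM4 (median from 0.18 to 0.02) and chromosome 8 at 140 to 150 Mb in PC9-AMG (from 0.18 to -0.01). HSP90AA1, a chaperone gene on chromosome 14 (102080738 to 102139749), stood at 5096 ± 10.7 TPM in PC9, 5898 ± 80.7 in PC9-BrM4 and 1562 ± 32.7 in PC9-AMG. It lies outside the 3 stretches above. It lies within the stretch of 26 genes lower in PC9-AMG than in PC9-BrM4, chromosome 14 from 101561351 to 103733668 (median -1.37).

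Removing the GC trend left the median of chromosome 14 at 70 to 80 Mb at -0.88 in PC9-AMG (before, -0.89), that of chromosome 12 at 50 to 60 Mb at -0.50 in PC9-BrM4 (before, -0.50) and that of chromosome 19 at 50 to 60 Mb at 0.41 in PC9-AMG (before, 0.47), which argues against GC content as the whole source for these 3 windows. All of the tested genes in the chromosome 14 stretches, 100%, were lower in PC9-AMG. Because the stretches were picked for being low, that share is close to given and decides nothing. A lost DNA copy and silencing of the region may each lie behind them and cannot be told apart, since DNA was not analysed here.

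The readthrough models ISY1-RAB43, MINOS1-NBL1 and BCL2L2-PABPN1 went with opposite changes of the models they overlap. Beside UGT1A8 and UGT1A10, listed at 0 in PC9, UGT1A6 was lower in PC9-BrM4 (291 and 203 TPM against 402 and 487), while UGT1A1 varied within lines (63.3 and 156 TPM against 84.4 and 3.11). The summed TPM over the overlapping models differed 1.01-fold for ISY1-RAB43, 1.02-fold for MINOS1-NBL1, 1.13-fold for BCL2L2-PABPN1 and 1.10-fold for UGT1A8 and UGT1A10. The ISY1-RAB43 model stood at 30.8 TPM in PC9, so its loss alone would have lowered the sum. The sum stayed at 64.6 TPM in PC9-BrM4 against 64.9 TPM in PC9, so reads shared between models may account for this fall. The other models are small beside their sums, such as 17.8 of 90.9 TPM for MINOS1-NBL1 in PC9-AMG. Their ratios would stay low without shared reads too, so the ratios alone decide nothing. Rises of these models alone would have raised the sums, which did not rise. The sums stood at 90.9 ± 1.53 against 92.6 ± 1.17 TPM for MINOS1-NBL1 and 108 ± 0.922 against 122 ± 2.78 TPM for BCL2L2-PABPN1. For UGT1A the sum was 455 ± 1.57 against 499 ± 3.93 TPM in PC9. Reads shared between models may therefore account for these rises as well. The level of each model stays uncertain.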
